A study of Trachinotus blochii with 22 samples.

How the data were processed

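Small RNA sequencing libraries (single-end reads of 50 bases) from the liver of golden pompano were studied through the table of miRNA values that the authors deposited. Per the labels, RNA was extracted with Trizol. The authors' processing notes name Bowtie without a version, and the reference build, annotation and read counter are not given in the sources used here. The table holds 2108 entries, 1809 named after known miRNAs of 123 species prefixes and 299 predicted, in 22 library columns and 8 columns of group means. No reference genome was used.

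The values are called TPM in the name of the deposited table, but they are CPM made by the authors, the reads of an entry scaled to a fixed sum per library. Each library column has the same fixed sum, and all values are whole multiples of 1 read within 0.01, so that no scaling by length was made and read numbers could be recovered. Libraries held 17.5 to 33.8 M assigned reads, a read counting once in each entry it matches, which makes 1 read worth 0.0296 to 0.0572 CPM, with a floor of 3 reads. Near-identical entries share reads, so they are not separate measurements. 708 repeated rows were removed, which left 1400 distinct rows. Of the 8 deposited group means, 6 equal the mean of their libraries to within rounding. The means of normoxia 0 h and rapid reoxygenation 12 h differ from it by up to 12910 and 20335 CPM, because 3 times each mean minus its 2 columns leaves a further library with that same sum and 0 negative entries. That library was not reconstructed, and those means are given as the authors' deposited values, with log2 ratios of them.

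Library columns were joined to the groups of the labels by the times in the column names and the number of libraries per group. The columns taken as normoxia 0 h and their mean carry no time in their names. They were placed by the number of libraries alone, on which every comparison with normoxia 0 h rests. The letters before the times are not explained in the labels, which is a limit on every comparison. The 2 columns of normoxia 0 h are numbered 2 and 3 in the table, and the library numbers used here are those of the table.

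Entries with at least 1 CPM in at least 2 libraries were tested, 602 in all, with 240 family names. log2(CPM + 1) values were fitted in limma 3.58.1 (R 4.3.3) with a mean-variance trend and all 8 groups in one fit, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. There were 11 comparisons of groups and 2 tests of a difference between comparisons. Comparisons at 12 h with normoxia share the same 3 normoxia libraries, and those at 0 h the same 2. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads. Figures were made with matplotlib 3.10.9 in Python 3.11.15, and the random seed was 101.

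Per comparison, the text names the 10 largest rises and the 10 largest falls among entries past the threshold with a mean of at least 10 CPM over the 2 groups. List members and the miRNAs given throughout stand by the most abundant entry of their family. Other names stand for the entry that met the rule, which need not be the most abundant. Where fewer than 5 passed, it also names the 5 with the smallest unadjusted p, which did not pass. List members past a threshold are named as examples, and miR-210, miR-462, miR-731, miR-122, miR-451, miR-144, miR-21, miR-142 and miR-217 are given throughout. The comparisons, their tests, this naming rule, the miRNA lists and the alternatives were fixed before the data were examined, except for 8 alternatives named below. The tests and relations by which patterns are weighed at the end were set up later.

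17 lists of miRNAs were written from general knowledge. They were hypoxia-responsive (16 of 18 members tested), hepatocyte (11 of 13), erythroid (2 of 3), leukocyte (7 of 7), muscle (4 of 6), pancreas (4 of 5), neural (4 of 5), vascular and stromal (7 of 9), epithelial miR-200 (5 of 5), let-7 (12 tested), miR-17-92 and paralogues (16 of 21), miR-30 (5 of 5), miR-29 (2 of 4), miR-10/99/100/125 (12 of 13), lipid and glucose metabolism (9 of 18), miR-34 (1 of 4) and miR-430 (0 of 5). The 13 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, 1 entry per family name (the most abundant, whichever arm it is), adjusted over the lists. let-7 and let-7b, let-7e and let-7k, miR-17 and miR-17a, miR-92 and miR-92b, and miR-125 and miR-125b are near copies (log2 values within 0.2 in every library) yet count as separate members. The hypoxia-responsive list shares miR-155 with the leukocyte list, miR-199 with the vascular and stromal list and 4 members with the lipid and glucose metabolism list, which also holds miR-122 and members of the miR-29 and miR-34 lists. A count adjusted over the list alone comes from adjusting the limma p-values within that list. For the miR-34 list, with 1 tested member, this is the unadjusted p.

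In all 20 pairs of libraries of the same group and 211 pairs between groups, differences exceeded counting noise (chi-square per degree of freedom at least 224 and 292), so no library was a copy of another. The test was tried on simulated data with the depths and spread of these libraries, 200 of 602 entries changed. With changed entries under 1000 CPM, limma recovered 28.4%, 77.6% and 84.8% of 2-, 4- and 8-fold changes for hypoxia against normoxia at 12 h with 8 false calls among 402 unchanged entries, 22.4%, 70.1% and 86.4% with 5 false calls at 0 h, and 16.4%, 59.7% and 77.3% with 4 for gradual against rapid reoxygenation at 12 h. When abundant entries were changed as well, the same 3 comparisons gave 3, 15 and 137 false calls by limma and 6, 7 and 4 by edgeR, and the cause of the 137 was not tested. camera called the changed list of 12 members and not the unchanged one in each of these 3 comparisons. The simulated entries varied independently of each other, so this does not show how camera behaves on members that vary together.

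The tests were repeated with pseudocounts of 0.1 and 10, no filter, a filter at 10 CPM, quantile normalization, TMM factors, identical rows kept, robust empirical Bayes, the replicate number as a block, only the groups compared, edgeR, DESeq2, each library left out in turn, and for lists an estimated correlation. Chosen after seeing the data were near-identical entries merged, totals without miR-122, the authors' means as values (log2 ratios with no test), normoxia 0 h left out of the fit and, for the difference between 12 h and 3 h in gradual against rapid reoxygenation, both libraries with almost no miR-217 left out, for lists also with an estimated correlation. Also chosen then were near-copy list members counted once, and an estimated correlation for list calls made only without 1 library. As deposited, the median change of all tested entries lay between −0.12 (gradual reoxygenation against normoxia at 12 h) and 0.02. Quantile normalization moved it from −0.06 to 0.11 in normoxia 12 h against 0 h and from 0.02 to 0.12 in gradual reoxygenation 3 h against hypoxia 0 h.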

Results

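Small RNA was sequenced from the liver of golden pompano (Trachinotus blochii), a marine fish kept in aquaculture. Fish were held in normal oxygen (normoxia), under hypoxic stress, or under rapid or gradual return of oxygen after hypoxia, and the study asked how miRNA levels followed these treatments. The 22 libraries fall into 8 groups. Normoxia at 0 h and rapid reoxygenation at 12 h have 2 libraries each. Normoxia at 12 h, hypoxia at 0 h and 12 h, rapid reoxygenation at 3 h, and gradual reoxygenation at 3 h and 12 h have 3 each. The labels do not say from which moment the hours are counted, and no normoxia or hypoxia library at 3 h was used here. Nothing in the labels says that each library came from a separate fish, so p-values measure only the spread between these samples, which may be technical. Libraries held 17.5 to 33.8 M reads assigned to miRNA entries, a read counting once in each entry it matches, so that 1 read was worth 0.0296 to 0.0572 CPM (reads of an entry, scaled to a fixed sum per library). Levels are given in CPM as mean ± SD, with n libraries. Changes are on the log2(CPM + 1) scale with their standard error, which understates the change of low entries, and adjusted p-values come from limma with Benjamini-Hochberg adjustment over 602 entries.

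miR-122, the leading miRNA of hepatocytes, was the most abundant, at 87809.6 ± 14791 CPM over the 22 libraries (oha-miR-122-5p). The values of its 16 entries sum to 17.5% to 51.6% of a library's total, in which a read that matches several entries counts once in each, so this is not a share of distinct reads. Entries of miR-122b (rno-miR-122b, 58419 ± 9966 CPM) were counted with miR-122. miR-22a (dre-miR-22a-3p) followed at 25922 ± 3674 CPM, miR-146a (dre-miR-146a) at 23590.4 ± 14292 CPM, miR-143 (efu-miR-143) at 22390.5 ± 11057 CPM, miR-192 (ola-miR-192-5p) at 19953 ± 17924 CPM and miR-100 (ola-miR-100) at 19483 ± 2937 CPM. Library 2 of normoxia 0 h stood apart from the rest. Its entries deviated from the median library by a root mean square of 1.34 log2 units, against 0.345 to 0.868 in the other 21, and it held 37563 CPM of miR-122 and 98914 CPM of miR-192. miR-217, a miRNA of pancreatic acinar cells, was at 5.35 CPM in library 1 of gradual reoxygenation 3 h and at 7.78 CPM in library 1 of rapid reoxygenation 12 h, against 165 to 2079 CPM in the other 20 (hsa-miR-217-5p).

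**Figure D1:**
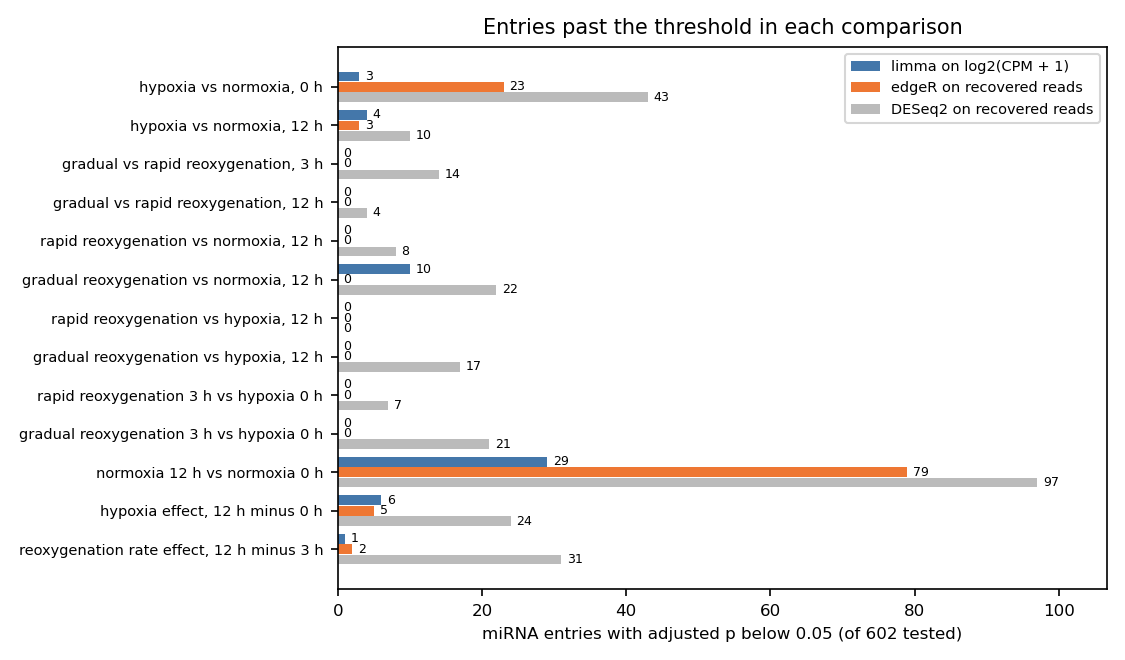
Horizontal bars give the number of miRNA entries with an adjusted p below 0.05, of 602 tested, for each of 11 comparisons of groups and 2 tests of a difference between comparisons, by limma (blue), edgeR (orange) and DESeq2 (grey). Counts range from 0 to 29 by limma, 0 to 79 by edgeR and 0 to 97 by DESeq2, with the highest of each in normoxia at 12 h against normoxia at 0 h.

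Hypoxia was first compared with normoxia at 12 h. miR-144, which is made from one transcript together with miR-451 in developing red blood cells, was lower under hypoxia. It was at 43.6 ± 17.3 CPM (SD, n = 3) under hypoxia and at 232 ± 70.5 CPM (SD, n = 3) under normoxia (ola-miR-144), and fell by 2.40 ± 0.39 on the log2 scale (adjusted p = 0.00214), lower in all 3 hypoxia libraries than in any normoxia library. A predicted miRNA, novel_493, rose from 3.26 ± 4.22 to 43.2 ± 13.4 CPM (log2 change 3.80 ± 0.84, adjusted p = 0.0427). It no longer passed when library 1 or 3 of normoxia 12 h or any of the 3 libraries of hypoxia 12 h was left out (adjusted p = 0.267, 0.159, 0.180, 0.162 and 0.109), with edgeR (0.220), TMM factors (0.0543), pseudocount 10 (0.138), no filter (0.1003) or identical rows kept (0.0573), and over all alternatives its adjusted p lay between 0.00919 and 0.267, while miR-144 passed in all 6 fits that left out 1 library. In all, 4 entries passed, 1 higher and 3 lower. The 3 lower ones are miR-144 entries with nearly the same values in every library (ola-miR-144, pol-miR-144-5p at −2.39 and oni-miR-144b at −2.44). The entries tested of miRNAs often linked to low oxygen did not pass. The 5p arm of miR-210, a target of the hypoxia-inducible factor, was at 18.8 ± 2.16 CPM under hypoxia and 18.4 ± 2.93 CPM under normoxia (log2 0.03 ± 0.34). All miR-210 values here are of this entry (dre-miR-210-5p, a row also named gga-miR-210b-3p), because the 3p arm, the one best known to be induced by hypoxia, was at most 0.623 CPM in any library (dre-miR-210-3p) and was not tested. miR-462 and miR-731, a clustered pair that responds to hypoxia in zebrafish, differed by 0.13 ± 0.40 and −0.06 ± 0.39, and miR-21 by 0.18 ± 0.24. miR-122 (0.02 ± 0.19), the blood-cell miRNA miR-142 (−0.90 ± 0.44) and miR-217 (1.53 ± 1.52) did not pass either. Other entries of the miR-144 and miR-451 transcript and miR-2188 were lower without passing. miR-451 was at 3261 ± 735 against 11335 ± 3743 CPM (log2 −1.76 ± 0.51, adjusted p = 0.230), the 3p arm of miR-144 differed by −1.498 and miR-2188 by −1.54.

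Of the 16 measured members of the hypoxia-responsive list at 12 h, 11 were higher and 5 lower, 0 passed by limma over all entries, and 0 when adjusted over the list alone. The list as a whole did not pass with camera (median log2 change 0.11, adjusted p = 0.137), and at 0 h it did not either (11 of 16 higher, median 0.12, adjusted p = 0.469). Both measured members of the erythroid list, miR-144 and miR-451, were lower, 1 over all entries and 2 when adjusted over the list alone. In the neural list miR-138 (log2 0.80) passed only when adjusted over the list alone, 1 member against 0 over all entries. In the lipid and glucose metabolism list 7 of 9 members were higher (median 0.30, adjusted p = 0.137). In the group of miR-10, miR-99, miR-100 and miR-125 11 of 12 were higher (median 0.15, adjusted p = 0.137). Without library 2 of hypoxia 12 h that group was at an adjusted p of 0.0494, and at 0.513 with an estimated correlation. The leukocyte list had a median of −0.30 (adjusted p = 0.172), the let-7 list −0.21 (0.137), the vascular and stromal list 0.18 (0.218) and the miR-30 list 0.09 (0.702), the last turning to −0.00448 under quantile normalization. 0 of the 13 lists tested passed. By limma 23 entries had an unadjusted p under 0.05, where chance gives 30.1, and groups did not overlap for 12.8% of entries, where chance gives 10%. edgeR called 3 entries and DESeq2 called 10, 4 higher and 6 lower. With TMM factors, a scaling between libraries, the calls were 0 higher and 3 lower.

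**Figure D2:**
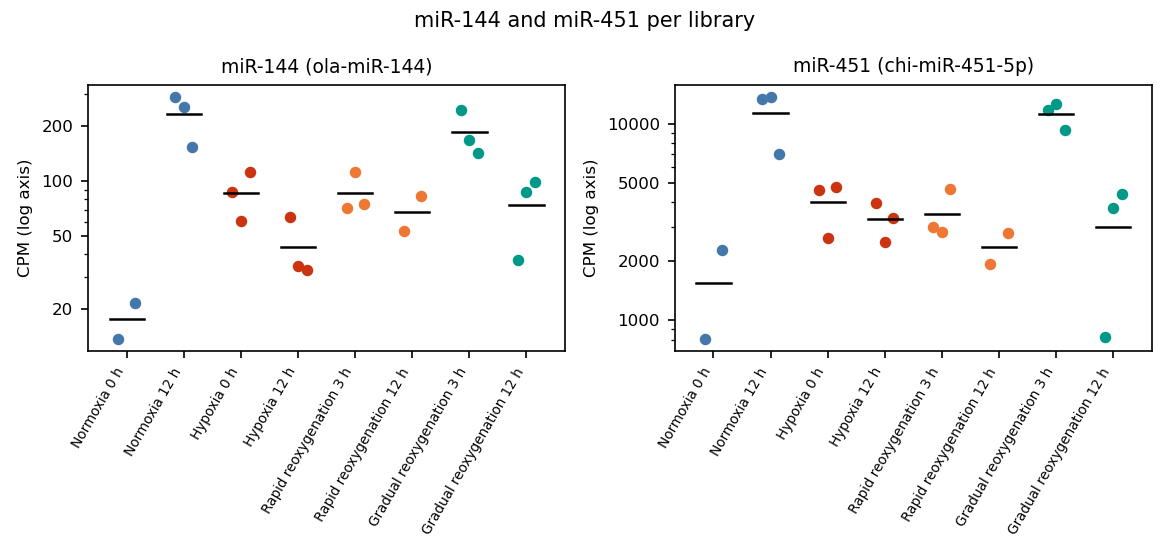
Each point is the level of miR-144 (left, ola-miR-144) or miR-451 (right, chi-miR-451-5p) in 1 library, in CPM on a log axis, and each line is the mean of its group. Normoxia 12 h and gradual reoxygenation 3 h have the highest group means of both, 232 and 185 CPM for miR-144 and 11335 and 11208 CPM for miR-451.

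At 0 h the difference in miR-144 had the opposite sign in the libraries used. miR-144 was higher under hypoxia, at 86.5 ± 25.7 CPM (SD, n = 3), than under normoxia, at 17.8 ± 5.58 CPM (SD, n = 2), a log2 change of 2.21 ± 0.44 (adjusted p = 0.0273). The 3 near-identical miR-144 entries were the 3 entries that passed, all higher, with pol-miR-144-5p at 2.24 and oni-miR-144b at 2.10. The authors' deposited table gives a mean of 41.5 CPM for normoxia 0 h, which includes a further library not analysed here. That library must therefore hold more miR-144 than the mean of the 2 used. On the deposited means the log2 ratio of hypoxia to normoxia for miR-144 is 1.04, against 2.22 on the libraries used, and for miR-451 0.65 against 1.36, with no test. miR-451 was at 3980.2 ± 1186 against 1550.0 ± 1048 CPM (log2 1.497 ± 0.57, adjusted p = 0.307) and did not pass. miR-192 and miR-215, which share a seed sequence and mark liver and gut epithelium, were lower without passing, miR-192 at 18248 ± 5488 against 60608 ± 54173 CPM (log2 −1.41, adjusted p = 0.157) and miR-215 by −2.27 (adjusted p = 0.152). The other entries given for each comparison did not pass either. Their log2 changes were 0.59 ± 0.38 for miR-210, −0.31 for miR-462, 0.13 for miR-731, 0.36 for miR-21, 0.66 for miR-122, −0.06 for miR-142 and −0.52 for miR-217.

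The miR-200 family, a group of epithelial miRNAs, was lower as a list at 0 h (median log2 change −1.02, 5 of 5 members lower, camera adjusted p = 0.00205). Both erythroid members were higher, 1 over all entries and 2 when adjusted over the list alone. The miR-200 call was lost with the correlation estimated from the data (adjusted p = 0.998 with an estimated correlation), and without library 2 of normoxia 0 h (adjusted p = 0.223), the library that stood apart. miR-200a (−1.40) and miR-141 (−1.52) passed when adjusted over the list alone, 2 members against 0 over all entries. In the hepatocyte list 4 of 11 members passed when adjusted over the list alone, against 0 over all entries, with miR-122 higher and miR-194 (−1.52) and miR-22b (−0.996) among the 3 lower. The hepatocyte list had a median of −0.14 (adjusted p = 0.710). Unadjusted p was under 0.05 for 50 entries, where chance gives 30.1, and groups did not overlap for 16.1% of entries, where chance gives 20%. edgeR called 23 entries (3 higher, 20 lower), DESeq2 called 43 (4 higher, 39 lower), and limma with TMM factors called 3 higher and 1 lower. The limma count was 0, and miR-144 did not pass, without library 2 of normoxia 0 h (adjusted p = 0.289), library 1 (0.113) or library 3 (0.133) of hypoxia 0 h. It was 121 without library 3 of normoxia 0 h.

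Normoxia at 12 h was compared with normoxia at 0 h to show how levels differed between the 2 hours in normal oxygen. miR-144 rose from 17.8 ± 5.58 CPM (SD, n = 2) to 232 ± 70.5 CPM (SD, n = 3), a log2 change of 3.62 ± 0.44 (adjusted p = 5.59e-05). miR-451 rose from 1550.0 ± 1048 to 11335 ± 3743 CPM (2.99 ± 0.57, adjusted p = 0.00587), miR-2188 from 78.4 ± 60.3 to 444 ± 150.01 CPM (2.67 ± 0.55, adjusted p = 0.0110), and miR-122 from 54269 ± 23625 to 92571 ± 3129.6 CPM (0.84 ± 0.21, adjusted p = 0.0251). The authors' deposited means for normoxia 0 h, with the further library, are higher, at 41.5 CPM for miR-144 and 2543 CPM for miR-451. On them the log2 ratio is 2.46 for miR-144, against 3.63 on the libraries used, and 2.16 against 2.87 for miR-451, with no test. Among epithelial and stromal miRNAs, miR-200a fell from 4934 ± 5088 to 889.7 ± 326 CPM (−2.001), miR-141 by 2.14, miR-192 by 1.54 and miR-143, a smooth-muscle miRNA, by 1.46. The largest falls were of novel_493 (−3.83 ± 0.94) and miR-135b (−3.68 ± 1.03, adjusted p = 0.0446). In all 29 entries passed, 15 higher and 14 lower. The higher ones are entries of miR-144, miR-144b, miR-451, miR-2188 and miR-122, several of them near-identical, and novel_167. The lower ones also include 2 entries below 10 CPM, of miR-194 (aca-miR-194-1-3p, −1.55) and miR-429 (mdo-miR-429, −1.37). miR-210 did not pass (8.69 ± 4.86 to 18.4 ± 2.93 CPM, log2 1.09 ± 0.38, adjusted p = 0.0895). Nor did miR-462 (−0.94), miR-731 (0.01), miR-21 (−0.06), miR-142 (0.17) or miR-217 (−1.96).

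The miR-200 list was lower at 12 h in normoxia (median −1.48, 5 of 5 members lower, camera adjusted p = 0.00167; adjusted p = 0.991 with an estimated correlation). Without library 2 of normoxia 0 h, which held 8531 CPM of miR-200a against 1336 CPM in library 3, the list no longer passed (adjusted p = 0.722). 2 of its members fell over all entries and 5 when adjusted over the list alone. Of the vascular and stromal list, 1 of 7 members fell over all entries, against 2 lower and 1 higher when adjusted over the list alone (median −0.23, adjusted p = 0.923). Of the muscle list, 0 members passed over all entries and 2 when adjusted over the list alone (median −1.03, adjusted p = 0.574). Both erythroid members rose, 2 over all entries and 2 when adjusted over the list alone. In the hepatocyte list miR-122 rose and miR-192 fell over all entries, against 1 higher and 3 lower when adjusted over the list alone (median 0.04, although camera gave the direction as lower, adjusted p = 0.927). miR-128 passed only when adjusted over the neural list alone. miR-34b is the single tested member of the miR-34 list, so its limma p there (0.0244) is unadjusted. Adjusted over the lipid and glucose metabolism list it did not pass (0.0901). In the lists miR-34b (aca-miR-34b-5p) is the row that stands for miR-34a. The sign of the vascular and stromal median turned under quantile normalization, to 0.03. Unadjusted p was under 0.05 for 132 entries, where chance gives 30.1, and groups did not overlap for 26.1%, where chance gives 20%. edgeR called 79 entries (18 higher, 61 lower) and DESeq2 called 97 (28 higher, 69 lower), limma with TMM factors called 10 higher and 1 lower, and with quantile normalization 11 higher and 4 lower. The limma count was 4 without library 2 of normoxia 0 h, 193 without library 3 of normoxia 0 h, and 8, 9 and 14 without libraries 1, 2 and 3 of normoxia 12 h. miR-144 passed in each of these 5 fits. Without library 2 of normoxia 0 h miR-451 and miR-2188 (adjusted p = 0.258), miR-122 (0.415), miR-200a (0.497), miR-192 (0.538), miR-141 (0.464), miR-143 (0.355), novel_493 (0.355) and miR-135b (0.611) did not pass. Several calls were also lost without library 1, 2 or 3 of normoxia 12 h, namely miR-122 (oha-miR-122-5p, 0.0631, 0.0940 and 0.0665), miR-200a (0.0523, 0.134 and 0.0521), miR-192 (0.0979, 0.0940 and 0.0595) and miR-135b (0.0697, 0.134 and 0.125). Of the same libraries, miR-143 was lost without 1 or 2 (0.0631 and 0.0940), miR-141 without 2 or 3 (0.125 and 0.0521), novel_493 without 1 or 3 (0.0971 and 0.0715) and miR-2188 without 1 (0.0523). At 12 h against 0 h under hypoxia, limma called 0 entries (33 at an unadjusted p under 0.05, smallest adjusted p = 0.403), and miR-144 differed by −0.995 ± 0.39 (adjusted p = 0.772).

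Whether the difference between hypoxia and normoxia itself differed between 12 h and 0 h was tested in the same fit. It did for miR-144, by −4.61 ± 0.59 for ola-miR-144 (adjusted p = 1.11e-04), for its 3p arm, by −2.87 ± 0.66 for mmu-miR-144-3p (adjusted p = 0.0498), and for miR-451, by −3.26 ± 0.76 (adjusted p = 0.0498). In all 6 entries passed, each more negative at 12 h, and they belong to miR-144, miR-144b and miR-451. On the deposited means the same difference is −3.43 for ola-miR-144, against −4.61 on the libraries used, and −2.44 against −3.16 for miR-451. miR-210 (−0.55 ± 0.50), miR-462 (0.44), miR-731 (−0.19), miR-21 (−0.18), miR-122 (−0.64), miR-142 (−0.84) and miR-217 (2.05) did not pass. The difference for the miR-200 list was positive (median 1.41, camera adjusted p = 3.99e-04; adjusted p = 0.920 with an estimated correlation), and was lost without library 2 of normoxia 0 h (adjusted p = 0.703). 2 members of the miR-200 list, miR-200a (2.001) and miR-141 (2.04), passed when adjusted over the list alone and 0 over all entries. The leukocyte list, which did not pass with all libraries, did as lower without library 2 of normoxia 0 h, but not with an estimated correlation. That fit leaves 1 library of normoxia 0 h. Both erythroid members passed over all entries and when adjusted over the list alone. miR-138 (1.14) passed only when adjusted over the neural list alone. miR-34b (1.502) is the single tested member of the miR-34 list, so its limma p there (0.0230) is unadjusted. Adjusted over the lipid and glucose metabolism list it did not pass (0.104). Unadjusted p was under 0.05 for 54 entries, edgeR called 5 (1 higher, 4 lower), DESeq2 called 24 and limma with TMM factors 4 (1 higher, 3 lower). The limma count was 92 without library 3 of normoxia 0 h, and 3 when any 1 of the 3 libraries of hypoxia 0 h was left out or without library 2 or 3 of hypoxia 12 h. miR-144 passed in all 11 of these fits, the 3p arm in 3 (adjusted p 0.0655 to 0.236 in the other 8) and miR-451 in 2 (0.0613 to 0.320 in the other 9). The highest of both came without library 2 of normoxia 0 h.

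**Figure D3:**
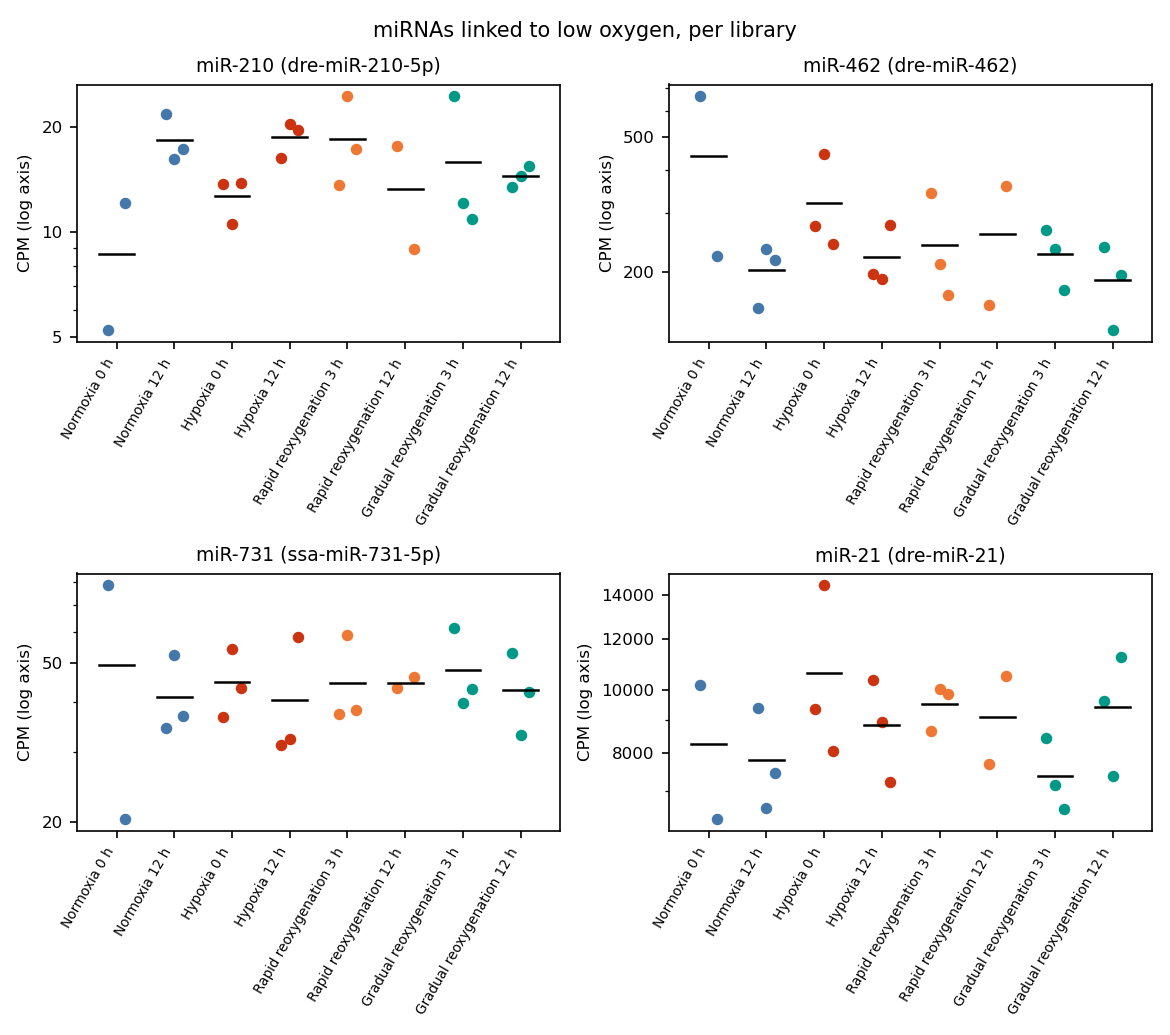
Each point is the level in 1 library, in CPM on a log axis, of miR-210 (dre-miR-210-5p), miR-462 (dre-miR-462), miR-731 (ssa-miR-731-5p) or miR-21 (dre-miR-21), and each line is a group mean. Means of the 5p arm of miR-210 lie between 8.69 CPM at normoxia 0 h and 18.8 CPM at hypoxia 12 h, and 0 of these 4 miRNAs passed the test in any of the comparisons.

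Gradual and rapid reoxygenation were compared at 3 h. miR-34a, a miRNA induced by the tumour suppressor p53, was at 40.6 ± 6.42 CPM (SD, n = 3) after gradual and 13.2 ± 3.11 CPM (SD, n = 3) after rapid reoxygenation (log2 1.56 ± 0.40, adjusted p = 0.173), and the near-identical miR-34b entry gave 1.56. miR-451 was at 11208 ± 1705 against 3477 ± 1023 CPM (1.72 ± 0.51, adjusted p = 0.242), miR-144 at 185 ± 53.02 against 86.2 ± 22.8 CPM (1.08, adjusted p = 0.307), and its 3p arm differed by 1.54. miR-153b, a miRNA best known from neurons, was at 16.5 ± 24.1 against 148 ± 10.7 CPM (−4.17 ± 1.06, adjusted p = 0.173). miR-210 (−0.26), miR-462 (−0.05), miR-731 (0.10), miR-21 (−0.37), miR-122 (0.08) and miR-142 (0.91) did not pass. 0 entries passed by limma, with 57 at an unadjusted p under 0.05 where chance gives 30.1, and 0 by edgeR, while DESeq2 called 14. The smallest adjusted p was 0.0996, of the predicted entry novel_431, which was chosen after its values were seen and lies at 1.38 ± 0.451 against 0.109 ± 0.0257 CPM. Groups did not overlap for 19.6% of entries, where chance gives 10%.

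As lists, the pancreas miRNAs were lower after gradual reoxygenation at 3 h (median −2.52, 4 of 4 lower, camera adjusted p = 0.0254; adjusted p = 0.297 with an estimated correlation), with miR-217 at 313 ± 278 against 1277 ± 217.1 CPM and miR-216b at 494 ± 413 against 1779 ± 270.1 CPM. 3 members passed when adjusted over the list alone and 0 over all entries. The miR-200 list was also lower (median −0.76, 5 of 5 lower, adjusted p = 0.0147; adjusted p = 0.488 with an estimated correlation). Both list calls were lost without library 1 of gradual reoxygenation 3 h, one of the 2 libraries with almost no miR-217 (adjusted p = 0.296 and 0.0740). miR-10 (−3.22) and miR-10a (−3.63) passed when adjusted over their list alone, 2 members against 0 over all entries (list adjusted p = 0.173), and their rapid reoxygenation levels were 36.8 ± 55.3 and 80.4 ± 120.4 CPM. Both erythroid members and miR-34b, of the miR-34 and the lipid and glucose metabolism lists, also passed when adjusted over their lists alone and not over all entries. Of the lists that did not pass with all libraries, some did, all lower, when 1 library was left out, namely muscle (0.0331) and the group of miR-10 and miR-100 (0.0402) without library 1 and miR-17-92 (0.0136) without library 3 of rapid reoxygenation 3 h, and again the group of miR-10 and miR-100 (0.0488) without library 2 of gradual reoxygenation 3 h. With an estimated correlation these lists were at 0.181 for muscle, 0.555 and 0.373 for the group of miR-10 and miR-100, and 0.438 for miR-17-92. The limma count was 6 without library 1 of rapid reoxygenation 3 h and 2 without library 1 of gradual reoxygenation 3 h, and 9 in a fit of these 2 groups alone.

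**Figure D4:**
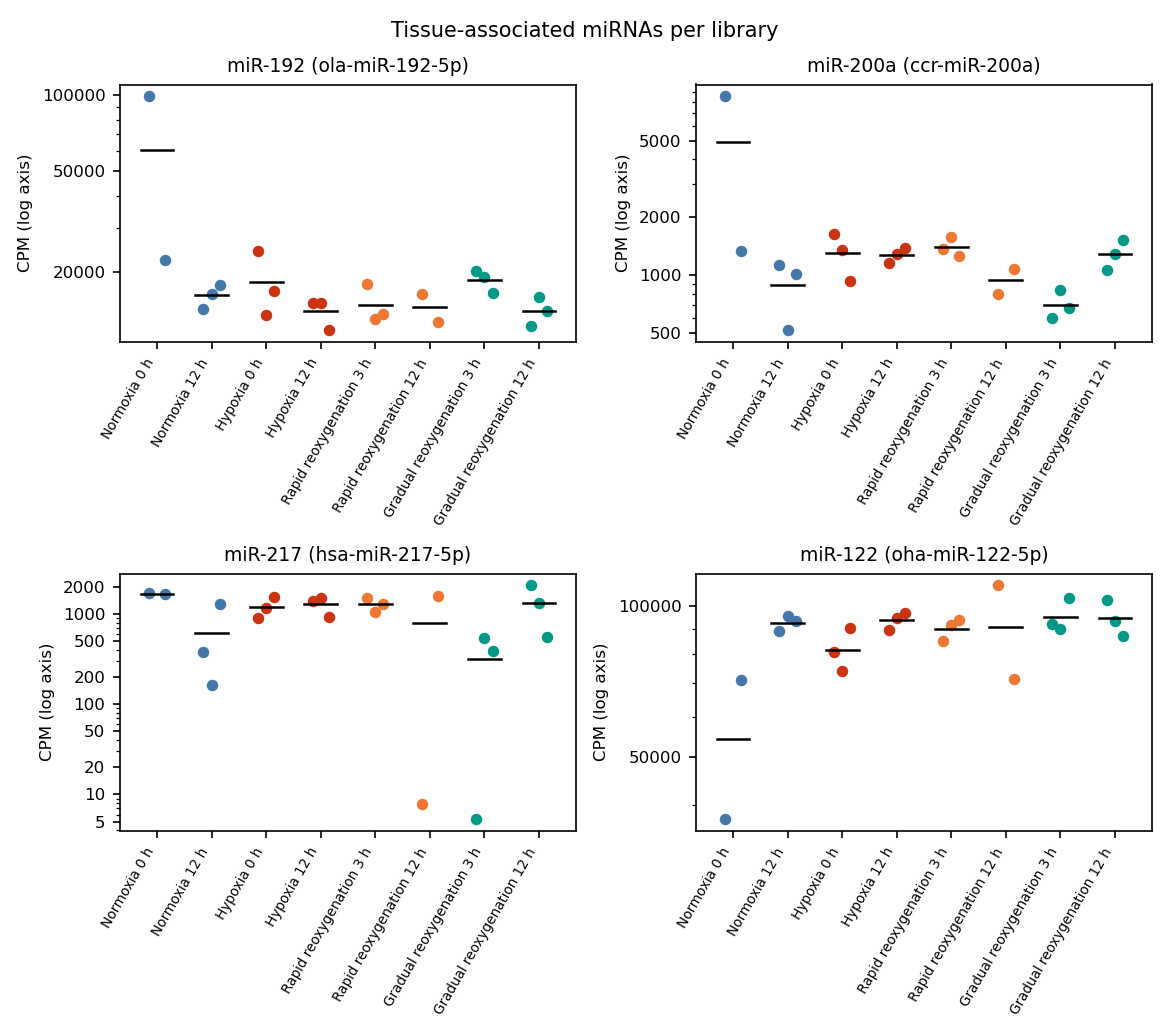
Each point is the level in 1 library, in CPM on a log axis, of miR-192 (ola-miR-192-5p), miR-200a (ccr-miR-200a), miR-217 (hsa-miR-217-5p) or miR-122 (oha-miR-122-5p), and each line is a group mean. Library 2 of normoxia 0 h has the highest miR-192 and miR-200a and the lowest miR-122, and miR-217 is at 5.35 and 7.78 CPM in 1 library each of gradual reoxygenation 3 h and rapid reoxygenation 12 h.

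At 12 h, the entries nearest to passing between gradual and rapid reoxygenation, among those of at least 10 CPM, were of miR-142, at 5.71 ± 1.95 CPM (SD, n = 3) after gradual and 27.9 ± 21.4 CPM (SD, n = 2) after rapid reoxygenation for gga-miR-142-5p (log2 −1.92 ± 0.51, adjusted p = 0.184). The most abundant miR-142 entry, pbv-miR-142-5p, differed by −1.55 ± 0.50 (adjusted p = 0.402), and miR-146b, which acts in the innate immune response, by −1.71. miR-144 was at 74.5 ± 32.8 against 68.3 ± 20.6 CPM (0.04 ± 0.44) and miR-451 at 2991 ± 1904 against 2363 ± 603 CPM (0.04 ± 0.57). miR-210 (0.18), miR-462 (−0.37), miR-731 (−0.09), miR-21 (0.05) and miR-122 (0.09) did not pass. miR-217 differed by 3.29 ± 1.70 (adjusted p = 0.789). By limma 0 entries passed, with 41 at an unadjusted p under 0.05 where chance gives 30.1 and a smallest adjusted p of 0.0617, while edgeR called 0 and DESeq2 called 4. The authors' deposited table gives a mean of 29.2 CPM of pbv-miR-142-5p for rapid reoxygenation 12 h, which includes a further library not analysed here, where the mean of the 2 libraries used was 41.0 CPM. The deposited means of that group are also lower for miR-144 (50.1 CPM) and miR-451 (1839 CPM). For both they lie farther below the means after gradual reoxygenation, with no test.

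At 12 h the leukocyte list was lower after gradual than after rapid reoxygenation (median −0.68, 6 of 7 lower, camera adjusted p = 0.0349; adjusted p = 0.759 with an estimated correlation), with 3 members passing when adjusted over the list alone and 0 over all entries. It was lost without library 2 of rapid reoxygenation 12 h (adjusted p = 0.539) and without library 1 (0.0624) or 2 (0.355) of gradual reoxygenation 12 h. The pancreas list was higher (median 2.18, 4 of 4 higher, adjusted p = 0.0187; adjusted p = 0.606 with an estimated correlation) and was lost without library 1 of rapid reoxygenation 12 h, the other library with almost no miR-217 (adjusted p = 0.583), and without library 2 of gradual reoxygenation 12 h (0.0903). The miR-200 list was higher (median 0.51, 5 of 5 higher, adjusted p = 0.0349; adjusted p = 0.836 with an estimated correlation) and was lost without library 1 (0.102) or 2 (0.353) of rapid or library 2 (0.180) or 3 (0.196) of gradual reoxygenation 12 h. The let-7 list did not pass with all libraries but did, as higher, without library 2 of rapid reoxygenation 12 h, which leaves 1 library. It also did without library 3 of gradual reoxygenation 12 h (0.00767, or 0.738 with an estimated correlation). With an estimated correlation neither call was made. Groups did not overlap for 20.8% of entries, where chance gives 20%. Without library 1 or library 2 of rapid reoxygenation 12 h limma called 3 or 8 entries, and 4 with normoxia 0 h left out of the fit.

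The difference between gradual and rapid reoxygenation was then compared between 12 h and 3 h. 1 entry passed, novel_431, by −2.35 ± 0.34 (adjusted p = 0.00132). This predicted entry, named after its values were seen, was at 1.38 ± 0.451 CPM after gradual and 0.109 ± 0.0257 CPM after rapid reoxygenation at 3 h, and at 0.0125 ± 0.0216 and 1.44 ± 0.239 CPM at 12 h, so it rests on few reads. miR-142 did not pass (gga-miR-142-5p, −2.64 ± 0.69, adjusted p = 0.133), and neither did miR-217 (6.81 ± 2.28, adjusted p = 0.198), miR-451 (−1.68), miR-144 (−1.05), miR-210 (0.44), miR-462 (−0.32), miR-731 (−0.19), miR-21 (0.42) or miR-122 (0.01). The pancreas list (median 4.71, camera adjusted p = 0.00178; adjusted p = 0.325 with an estimated correlation) and the miR-200 list (median 1.29, adjusted p = 0.00178; adjusted p = 0.478 with an estimated correlation) were more positive at 12 h. Both passed in each of the 11 fits that left out 1 library. The 2 libraries with almost no miR-217 push this difference the same way, however. Both were left out in a fit chosen after the data were seen, which leaves 1 library of rapid reoxygenation 12 h, library 2. There the pancreas list did not pass (median 0.91), and the miR-200 list had a median of 1.15. miR-142 (gga-miR-142-5p) differed by −3.43, and the leukocyte list had a median of −1.15. With an estimated correlation none of these lists passed. The rapid library left at 12 h had the highest leukocyte list median of all libraries (1.27 log2 units), so the miR-142 and leukocyte differences in that fit rest on it. 3 pancreas members passed when adjusted over the list alone, miR-217, miR-216b (5.57) and miR-216a (3.85), against 0 over all entries. 2 leukocyte members, and miR-34b in the miR-34 and the lipid and glucose metabolism lists, passed when adjusted over their lists alone and 0 over all entries. Further lists that did not pass with all libraries did when 1 library was left out, miR-17-92 as higher without library 3 of rapid reoxygenation 3 h (0.0253), let-7 as higher without library 2 of rapid reoxygenation 12 h (0.0149), and leukocyte as lower without library 1 of rapid (0.0156) or library 3 of gradual (0.0480) reoxygenation 12 h. These list calls were not made with an estimated correlation. edgeR called 2 entries and DESeq2 called 31, and 63 had an unadjusted p under 0.05 by limma. The limma count was 6 without library 1 of rapid reoxygenation 3 h, 6 without library 1 and 15 without library 2 of rapid reoxygenation 12 h, and 0 with the filter at 10 CPM, which novel_431 does not reach.

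Against normoxia at 12 h, levels of miR-451, miR-144 and several other entries were lower after gradual reoxygenation. miR-451 fell from 11335 ± 3743 CPM (SD, n = 3) to 2991 ± 1904 CPM (SD, n = 3), a log2 change of −2.18 ± 0.51 (adjusted p = 0.0389). miR-2188 fell from 444 ± 150.01 to 119 ± 68.7 CPM (−2.07 ± 0.49), the 3p arm of miR-144 from 37.6 ± 13.3 to 9.66 ± 5.72 CPM (−1.98 ± 0.44) and miR-144 from 232 ± 70.5 to 74.5 ± 32.8 CPM (−1.70 ± 0.39), all at the same adjusted p. miR-15a, of the miR-15/16 family, fell from 34.1 ± 2.32 to 15.1 ± 0.937 CPM (−1.12 ± 0.28, adjusted p = 0.0477). All 10 entries that passed were lower, and the 5 just given were lower in every gradual reoxygenation library than in any normoxia library. Another of the 10, novel_167, was named after its values were seen and lies below 10 CPM, at 1.98 ± 1.60 against 0.0493 ± 0.0575 CPM. miR-142 (−1.39 ± 0.44, adjusted p = 0.187), miR-210 (−0.32), miR-462 (−0.11), miR-731 (0.05), miR-21 (0.26), miR-122 (0.03) and miR-217 (1.40) did not pass. Both measured erythroid members fell, 2 over all entries and 2 when adjusted over the list alone, while 0 of 13 lists passed. The miR-200 list had a median of 0.54 (adjusted p = 0.0745). It passed without library 1 (0.0386) or 3 (0.0484) of normoxia or library 1 of gradual reoxygenation (0.00764). With an estimated correlation these were 0.917, 0.842 and 0.895. In the leukocyte list 1 member passed when adjusted over the list alone and 0 over all entries. 64 entries had an unadjusted p under 0.05, edgeR called 0 (smallest adjusted p = 0.0886) and DESeq2 called 22, 10 higher and 12 lower. The limma count was 0, and miR-451 did not pass, without library 1 (adjusted p = 0.209) or 2 (0.164) of normoxia 12 h or library 1 of gradual reoxygenation 12 h (0.247). The 3p arm of miR-144 was lost without library 3 of normoxia 12 h as well (0.0683). miR-15a passed in 0 of the 6 fits that left out 1 library (adjusted p 0.0958 to 0.247). The count was also 0 with quantile normalization, with no filter and in a fit of the 2 groups alone.

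Rapid reoxygenation at 12 h was set against the same 3 normoxia libraries. miR-2188 was at 83.3 ± 25.4 CPM (SD, n = 2) against 444 ± 150.01 CPM (SD, n = 3), a log2 difference of −2.37 ± 0.55 (adjusted p = 0.0839). miR-451 was at 2363 ± 603 CPM (−2.22 ± 0.57, adjusted p = 0.0939) and miR-144 at 68.3 ± 20.6 CPM (−1.73 ± 0.44, adjusted p = 0.0939). Whether these differ from the changes after gradual reoxygenation is the comparison of the reoxygenation groups at 12 h, in which neither miRNA passed. By limma 0 entries passed, with 27 at an unadjusted p under 0.05 where chance gives 30.1, while edgeR called 0 and DESeq2 called 8, 1 higher and 7 lower. The others given had log2 differences of −0.50 for miR-210, 0.26 for miR-462, 0.14 for miR-731, 0.22 for miR-21, −0.06 for miR-122, 0.16 for miR-142 and −1.89 for miR-217. Both erythroid members were lower, 0 over all entries and 2 when adjusted over the list alone. miR-34b (1.12), the row that stands for miR-34a, is the single measured member of the miR-34 list. It passed there only at its unadjusted p, 1 against 0 over all entries. 0 of 13 lists passed, though pancreas and let-7 did, as lower, without library 2 of rapid reoxygenation 12 h. That fit leaves 1 library in the group, and with an estimated correlation neither list passed in it. The miR-29 list had 2 measured members and was not tested (median −0.15). Groups did not overlap for 17.8% of entries, where chance gives 20%. With normoxia 0 h left out of the fit limma called 3 entries.

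Rapid reoxygenation at 12 h was next compared with hypoxia at 12 h. novel_493 was at 6.80 ± 7.75 CPM (SD, n = 2) against 43.2 ± 13.4 CPM (SD, n = 3), log2 −2.95 ± 0.94 (adjusted p = 0.883). miR-142 was at 27.9 ± 21.4 against 8.83 ± 1.57 CPM (gga-miR-142-5p, 1.34 ± 0.51) and miR-199b at 19.4 ± 1.97 against 35.5 ± 6.22 CPM (mdo-miR-199b-2-5p, −0.82). miR-144 differed by 0.67 ± 0.44, miR-451 by −0.46 ± 0.57, miR-210 by −0.53, miR-462 by 0.13, miR-731 by 0.20, miR-21 by 0.04, miR-122 by −0.08 and miR-217 by −3.42. Limma, edgeR and DESeq2 each called 0 entries, and 30 had an unadjusted p under 0.05 by limma where chance gives 30.1. The 2 groups did not overlap for 22.9% of entries, where chance gives 20%. The leukocyte list was higher after rapid reoxygenation (median 0.65, 6 of 7 higher, camera adjusted p = 0.0149; adjusted p = 0.518 with an estimated correlation), and the pancreas list lower (median −2.65, 4 of 4 lower, adjusted p = 0.00332; adjusted p = 0.327 with an estimated correlation), with 0 members of either passing over all entries or adjusted over the list alone. The leukocyte call was lost without library 2 of rapid reoxygenation 12 h (adjusted p = 0.504) or library 1 of hypoxia 12 h (0.111) and the pancreas call without library 1 of rapid reoxygenation 12 h, which held almost no miR-217 (adjusted p = 0.582). Without that library, which leaves 1 in the group, the let-7 list passed as higher, but not with an estimated correlation.

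Gradual reoxygenation at 12 h was set against the same hypoxia libraries. miR-148a (ggo-miR-148a) was at 146 ± 144 CPM (SD, n = 3) against 35.7 ± 6.34 CPM (SD, n = 3), log2 1.57 ± 0.49. miR-221 (pma-miR-221) was at 24.99 ± 2.29 against 46.5 ± 7.75 CPM (−0.86 ± 0.26), while another entry, efu-miR-221, was at 26.2 against 24.2 CPM. miR-19b was at 189 ± 28.5 against 108 ± 27.5 CPM (0.81 ± 0.27). The adjusted p of ggo-miR-148a, pma-miR-221 and miR-19b was 0.401 each. By limma 0 entries passed, with 59 at an unadjusted p under 0.05, while edgeR called 0 and DESeq2 called 17, 15 higher and 2 lower. The let-7 list was higher as a whole (median 0.32, 11 of 12 members higher, camera adjusted p = 7.72e-04; adjusted p = 0.823 with an estimated correlation). 2 pairs of its members are near copies, and counted once they leave 9 of 10 higher (adjusted p = 0.00558). Of the 12, 0 passed over all entries and 0 adjusted over the list alone. Without library 2 of gradual reoxygenation 12 h the let-7 list did not pass (adjusted p = 0.188). miR-144 differed by 0.71 ± 0.39, miR-451 by −0.42, miR-210 by −0.35, miR-462 by −0.24, miR-731 by 0.11, miR-21 by 0.09, miR-122 by 0.01, miR-142 by −0.49 and miR-217 by −0.13. Groups did not overlap for 23.8% of entries, where chance gives 10%.

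The 3 h reoxygenation groups had no hypoxia library at the same hour and were set against hypoxia at 0 h. For rapid reoxygenation the smallest adjusted p, equal to that of novel_487, was of miR-30a-3p (dre-miR-30a-3p, log2 1.02 ± 0.22, adjusted p = 0.0828). It was at 30.7 ± 9.26 CPM (SD, n = 3) against 14.2 ± 1.09 CPM (SD, n = 3). The miR-30 list, in which hsa-miR-30a-3p stands for miR-30a, had a median of 0.18 (adjusted p = 0.620). miR-199a differed by 0.50 ± 0.21 and miR-19a by 0.63 ± 0.26, both at adjusted p = 0.999. By limma 0 entries passed, with 16 at an unadjusted p under 0.05 where chance gives 30.1, while edgeR called 0 and DESeq2 called 7. The list of miR-17-92 and its paralogues, miRNAs tied to cell proliferation, was higher (median 0.22, 14 of 16 members higher, camera adjusted p = 0.0181; adjusted p = 0.793 with an estimated correlation). With its 2 pairs of near copies counted once 13 of 14 were higher (adjusted p = 0.0147). Of the 16, 0 passed over all entries and 0 adjusted over the list alone. The list call was lost without library 1 of rapid reoxygenation 3 h (adjusted p = 0.624), the library without which limma called 7 entries, and without library 2 of the same group (0.120), and limma called 1 without library 2 of hypoxia 0 h. The leukocyte list did not pass with all libraries but did, as lower, without library 1 (0.0298) or 3 (0.0252) of hypoxia 0 h. With an estimated correlation these were 0.632 and 0.912. miR-144 (0.01), miR-451 (−0.18), miR-210 (0.48), miR-462 (−0.41), miR-731 (−0.01), miR-21 (−0.12), miR-122 (0.14), miR-142 (−0.29) and miR-217 (0.11) did not pass. Groups did not overlap for 13.1% of entries, where chance gives 10%.

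Gradual reoxygenation at 3 h was also set against hypoxia at 0 h. miR-34a was at 40.6 ± 6.42 CPM (SD, n = 3) against 11.7 ± 5.37 CPM (SD, n = 3), log2 1.80 ± 0.40 (adjusted p = 0.0786), and the 3p arm of miR-144 at 51.3 ± 12.9 against 12.9 ± 1.57 CPM (1.88 ± 0.44, adjusted p = 0.0786). miR-451 was at 11208 ± 1705 against 3980.2 ± 1186 CPM (1.53 ± 0.51, adjusted p = 0.210), miR-144 differed by 1.09 ± 0.39 and miR-153b by −4.00 ± 1.06 (adjusted p = 0.173). By limma 0 entries passed, with 89 at an unadjusted p under 0.05 where chance gives 30.1, while edgeR called 0 and DESeq2 called 21, 7 higher and 14 lower. miR-210 (0.22), miR-462 (−0.47), miR-731 (0.09), miR-21 (−0.49), miR-122 (0.22), miR-142 (0.62) and miR-217 (−3.41) did not pass. Groups did not overlap for 31.6% of entries, where chance gives 10%. In this comparison limma called 6 entries without library 1 of hypoxia 0 h, 14 in a fit of the 2 groups alone, and 17 with normoxia 0 h left out of the fit.

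4 lists passed in that comparison, all at a camera adjusted p of 0.0343. The muscle list was lower (median −1.14, 4 of 4 lower; adjusted p = 0.168 with an estimated correlation), as was the pancreas list (median −2.15, 4 of 4 lower; adjusted p = 0.439 with an estimated correlation) and the miR-200 list (median −0.66, 5 of 5 lower; adjusted p = 0.594 with an estimated correlation), and the neural list was higher (median 0.64, 4 of 4 higher; adjusted p = 0.168 with an estimated correlation). The pancreas and miR-200 calls were lost without library 1 of gradual reoxygenation 3 h, which held almost no miR-217 (adjusted p = 0.282 and 0.164). All 4 were lost without library 1 of hypoxia 0 h (muscle and neural 0.0585, pancreas 0.0742, miR-200 0.151), and without library 3 of hypoxia 0 h the pancreas (0.0740) and neural (0.0725) calls were lost. The list of miR-10, miR-99, miR-100 and miR-125 did not pass but did, as lower, without library 2 of gradual reoxygenation 3 h (0.0407). With an estimated correlation this was 0.451. Adjusted over the list alone, 1 muscle member (miR-133, −1.70, at 0.408 ± 0.28 against 3.74 ± 1.93 CPM) and 2 neural members (the 5p arm of miR-124, 0.82, and miR-128, 0.79) passed, against 0 over all entries. Of those, miR-128 was the abundant one, at 754 ± 193 against 428 ± 22.6 CPM, while miR-124-5p was at 1.24 ± 0.876 against 0.194 ± 0.17 CPM, and the 3p arm, the better known neural marker, was not tested (mmu-miR-124-3p reached 1 CPM in 1 library). Both erythroid members, and miR-34b in the miR-34 and the lipid and glucose metabolism lists, passed when adjusted over their lists alone and not over all entries. miR-33 (0.69), of the lipid and glucose metabolism list, and miR-145 (−1.19), a smooth-muscle miRNA, also passed when adjusted over the list alone and not over all entries.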

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

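The tests of the miR-144 arm ratio, of the change of all entries beside miR-144, of the depth of normoxia 0 h library 2, of its hepatocyte share and of pancreas content were chosen only after the result was seen. The difference between hypoxia and normoxia itself differed between 12 h and 0 h in 6 entries and 1 list, by the test of the difference in limma and camera. The entries were pol-miR-144-5p (−4.63 ± 0.59, adjusted p = 1.11e-04), ola-miR-144 (−4.61 ± 0.59), oni-miR-144b (−4.54 ± 0.59), xla-miR-144-3p (−2.86 ± 0.65, adjusted p = 0.0498), mmu-miR-144-3p (−2.87 ± 0.66) and chi-miR-451-5p (−3.26 ± 0.76). The list was the epithelial miR-200 list (median 1.41, adjusted p = 3.99e-04; adjusted p = 0.920 with an estimated correlation). Between 0 h and 12 h ola-miR-144 changed by 3.62 in normoxia and by −0.995 under hypoxia, where it did not pass (adjusted p = 0.772). With the authors' deposited means, which hold a further normoxia 0 h library, the normoxia ratio for ola-miR-144 is 2.46 rather than 3.63. The difference is −3.43 rather than −4.61. Its size, and how far the opposite sign at 0 h holds, thus depend on that library, which must hold more miR-144 than the mean of the normoxia 0 h libraries used. Whether miR-144 would pass with that library, at 0 h or in the difference, was not tested. The difference between gradual and rapid reoxygenation differed between 12 h and 3 h for novel_431 (−2.35 ± 0.34, adjusted p = 0.00132), the pancreas list (median 4.71, adjusted p = 0.00178; adjusted p = 0.325 with an estimated correlation) and the epithelial miR-200 list (median 1.29, adjusted p = 0.00178; adjusted p = 0.478 with an estimated correlation).

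Of the 8 groups, normoxia 12 h and gradual reoxygenation 3 h have the highest means of miR-451, miR-144 and miR-2188, although no comparison of gradual reoxygenation 3 h passed for them. A few abundant entries are not the whole cause, since that would move all others alike, and where these miRNAs passed the median of all 602 entries changed by at most −0.12, against 1.70 or more for them. A different content of red cells in the tissue pieces may account for miR-451, miR-2188 and the 3p arm of miR-144, whose ratios were not shown to differ over the 8 groups (3 ratios, smallest adjusted permutation p = 0.334). With 2 or 3 libraries per group a difference could be missed. The ratio of miR-2188 to the 3p arm spanned 1.41 log2 units between group means (within-group SD 0.497, permutation p = 0.116). As miR-451 and miR-144 share a transcript, a change of that transcript would also keep their ratio, so the ratios cannot tell these apart. Within groups miR-451 moved with miR-2188 (22 libraries, Pearson r = 0.946, permutation p = 0.00142, adjusted 0.00852; Spearman 0.853, permutation p = 0.00331, adjusted 0.0199; r = 0.862 without the 2 farthest; 6 relations tested, Benjamini-Hochberg). For the 5p arm, whose ratio to the 3p arm gave a permutation p of 0.0983, red-cell content cannot be told apart from a change of miR-144 itself, because the spread within groups is wide, and an effect of oxygen or time on these miRNAs, which the design names, stays open.

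Library 2 of normoxia 0 h, on which the miR-200 result for hypoxia rests, stands apart for reasons that 3 tests narrow. After TMM scaling it still deviated from the median library by 1.43, against at most 0.886 in the others, so the share taken by a few entries is not the whole cause. Its depth, 24.8 M reads, lies within the range of the others. A lower share of hepatocytes alone would raise other cell types alike, but the miR-200 list lay 2.82 above the vascular and stromal list there, against at most 0.502 elsewhere. The miR-200 list was not the only one raised. List medians deviated there by 2.53 for miR-200, 1.39 for muscle, 0.513 for pancreas, 0.327 for leukocyte, −0.0366 for neural and −0.295 for vascular and stromal. A piece holding more epithelium, such as bile duct or gut, stays possible and was not tested.

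miR-217 is nearly absent in 2 libraries, without which the pancreas list was not called in single comparisons. With both left out, which leaves 1 library of rapid reoxygenation 12 h, the pancreas median in the difference between 12 h and 3 h went from 4.71 to 0.91. The scaling of these 2 libraries is not the cause, as the median of all tested entries there deviated by at most −0.12. Both miR-216a and miR-216b, 2 of 2 members of miR-216, have their 2 lowest values in the same libraries (miR-216b at 32.9 and 24.8 CPM, against 302 to 2590.0 CPM in the other 20). miR-375, the measured pancreas member outside their gene cluster, is only the 5th and 6th lowest there (0.394 and 0.425 CPM, against 0.283 to 59.2 CPM). For rapid reoxygenation 12 h the authors' deposited mean of miR-217, with a further library, is 524 CPM. Library 2 of that group lay 0.349 log2 units above the median library in miR-217. The further library, which was not reconstructed, may thus be low in miR-217 as well. Pieces that held little pancreatic tissue, which lies in or near the liver of many bony fishes, are possible. Lower expression cannot be told apart from this, since miR-216 and miR-217 come from one cluster and would fall together.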

How the results depend on the processing

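The alternatives with near-identical entries merged, totals without miR-122, the authors' means as values, normoxia 0 h left out of the fit and both libraries with almost no miR-217 left out (rate effect, for lists also with an estimated correlation), near-copy list members counted once and an estimated correlation for list calls made only without 1 library were chosen only after the data were seen. Of the 44 named results past the threshold, 0 changed sign in 858 alternatives and 593 of those stayed past the threshold. These results include near-identical entries. Some alternatives, such as robust empirical Bayes, identical rows kept or near-identical entries merged, leave the change itself as it was and cannot turn its sign. Of 188 named results that did not pass, 143 of 3913 alternatives changed sign and 184 passed. Counts of entries stayed within 1.5 times in 184 alternatives and moved in 89, and for lists in 97 and 37. With the authors' means as values, of 31 named results past the threshold in comparisons with normoxia 0 h or rapid reoxygenation 12 h 0 changed sign, but all 31 lay nearer 0 and 16 shifted by over 1 SD (ola-miR-144 from 2.22 to 1.04 in hypoxia vs normoxia at 0 h). Of 103 that did not pass, 18 changed sign and 7 shifted by over 1 SD. Pseudocount 0.1, identical rows kept and robust empirical Bayes moved no count of entries by more than that. Where counts moved the cause was not tested, except that leaving out libraries or groups leaves fewer samples.

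With pseudocount 10 limma called 0 entries in hypoxia vs normoxia at 0 h, 4 in gradual vs rapid reoxygenation at 3 h, 1 in rapid reoxygenation vs normoxia and 4 in gradual reoxygenation 3 h vs hypoxia 0 h. With no filter it called 4 in gradual vs rapid at 12 h, 4 in rapid vs normoxia, 0 in gradual vs normoxia, 4 in rapid vs hypoxia at 12 h, 11 in normoxia 12 h vs 0 h, 3 for the hypoxia effect and 2 for the rate effect. The filter at 10 CPM gave 4 in gradual 3 h vs hypoxia 0 h and 0 for the rate effect. Quantile normalization gave 1 in gradual vs rapid at 12 h, 1 in rapid vs normoxia, 0 in gradual vs normoxia, 1 in rapid vs hypoxia, 15 in normoxia 12 h vs 0 h and 3 for the hypoxia effect. TMM factors gave 11 in normoxia 12 h vs 0 h and 2 for the rate effect. Fits of only the groups compared gave 0 in hypoxia vs normoxia at 0 h, 9 in gradual vs rapid at 3 h, 0 in gradual vs normoxia, 14 in gradual 3 h vs hypoxia 0 h and 3 in normoxia 12 h vs 0 h.

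edgeR called 23 in hypoxia vs normoxia at 0 h, 0 in gradual vs normoxia, 79 in normoxia 12 h vs 0 h and 2 for the rate effect. DESeq2 called 43 and 10 in hypoxia vs normoxia at 0 h and 12 h, 14 and 4 in gradual vs rapid at 3 h and 12 h, 8 in rapid vs normoxia, 22 in gradual vs normoxia, 17 in gradual vs hypoxia, 7 and 21 in rapid and gradual 3 h vs hypoxia 0 h, 97 in normoxia 12 h vs 0 h, 24 for the hypoxia effect and 31 for the rate effect. Merging near-identical entries (602 to 487) gave 1 in gradual vs rapid at 12 h and 17 in normoxia 12 h vs 0 h. Totals without miR-122 gave 1 in gradual vs rapid at 12 h, 1 in rapid vs normoxia, 4 in gradual 3 h vs hypoxia 0 h and 7 for the rate effect. With normoxia 0 h left out of the fit, counts were 1 and 4 in gradual vs rapid at 3 h and 12 h, 3 in rapid vs normoxia, 16 in gradual vs normoxia, 1 in rapid vs hypoxia, 17 in gradual 3 h vs hypoxia 0 h and 7 for the rate effect. Both libraries with almost no miR-217 left out leaves 1 library of rapid reoxygenation 12 h. The pancreas median for the rate effect then went from 4.71 to 0.91, and no list was called with an estimated correlation.

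The replicate number as a block, which needs libraries paired by number, gave 1 in gradual vs rapid at 3 h, 1 at 12 h, 1 in rapid vs normoxia, 1 in rapid vs hypoxia and 9 in gradual 3 h vs hypoxia 0 h, and for lists 1 in hypoxia vs normoxia at 12 h, 1 in gradual vs rapid at 3 h, 1 in gradual vs normoxia, 3 in rapid vs hypoxia and 2 in gradual 3 h vs hypoxia 0 h. The numbers do not pair the libraries (57 same-number pairs, median r −0.06, range −0.47 to 0.49, 11 over 0.1). The normoxia 0 h libraries, whose numbers in the table and titles differ, did not enter it.

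Leaving out 1 library gave 0 to 121 entries in hypoxia vs normoxia at 0 h, 3 to 4 at 12 h, 0 to 6 and 0 to 8 in gradual vs rapid at 3 h and 12 h, 0 to 0 in rapid vs normoxia, 0 to 12 in gradual vs normoxia, 0 to 0 in rapid and in gradual vs hypoxia at 12 h, 0 to 7 and 0 to 6 in rapid and gradual 3 h vs hypoxia 0 h, 4 to 193 in normoxia 12 h vs 0 h, 3 to 92 for the hypoxia effect and 1 to 15 for the rate effect. Lists in the same order ranged 0 to 1, 0 to 1, 0 to 4, 0 to 3, 0 to 2, 0 to 1, 1 to 2, 0 to 1, 0 to 2, 0 to 5, 0 to 1, 1 to 1 and 2 to 3. Where 1 library is left in a group, it is assumed to vary like the other groups. With an estimated correlation 0 lists passed in every comparison, and of 21 list calls made only without 1 library 0 passed (smallest adjusted p = 0.181). Counting near-copy list members once changed no list call. Quantile normalization left 1 list in rapid vs hypoxia. Depth (1 read is at most 0.0572 CPM) limits entries such as novel_431, at 0.0125 ± 0.0216 CPM in gradual reoxygenation 12 h.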

Other observations

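The ratios and relations below that involve the 5p arm of miR-144, miR-142 or miR-122 were chosen only after the result was seen. miR-146a, which acts in the innate immune response, varied widely between libraries (9892 to 68553 CPM). Within groups, miR-451 also moved with the 3p arm of miR-144 (22 libraries, Pearson r = 0.809, permutation p = 0.0158, adjusted 0.0315; Spearman 0.673, permutation p = 0.0103, adjusted 0.0262; r = 0.613 without the 2 farthest) and its 5p arm (r = 0.835, permutation p = 0.00895, adjusted 0.0268; Spearman 0.695, permutation p = 0.0131, adjusted 0.0262; r = 0.620 without the 2 farthest). The 2 arms of miR-144 gave r = 0.702 (permutation p = 0.0926, adjusted 0.131; Spearman 0.401, permutation p = 0.177, adjusted 0.212; 0.428 without the 2 farthest). miR-451 and miR-142 gave r = 0.337 (permutation p = 0.366, adjusted 0.366; Spearman 0.208, permutation p = 0.519, adjusted 0.519; −0.209 without the 2 farthest), and miR-451 and miR-122 gave r = 0.401 (permutation p = 0.109, adjusted 0.131; Spearman 0.372, permutation p = 0.151, adjusted 0.212; 0.225 without the 2 farthest). These are among 6 relations adjusted by the Benjamini-Hochberg method. The ratio of the 5p arm of miR-144 to miR-451 gave a permutation p of 0.0249 over the 8 groups (adjusted 0.124 over 5 ratios).

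6 comparisons have 3 libraries on each side, which make 10 splits, too few for a share under 0.05. For hypoxia against normoxia at 12 h, 1 of the 10 splits gave as many entries as the real one, itself (4 entries, highest other 0), and for gradual reoxygenation against normoxia at 12 h also 1 (10 entries, highest other 0). In gradual against rapid reoxygenation at 3 h (57 entries at an unadjusted p under 0.05 by limma, 0 by edgeR, 14 by DESeq2), gradual reoxygenation against hypoxia at 12 h (59, 0 and 17), and rapid (16, 0 and 7) and gradual (89, 0 and 21) reoxygenation 3 h against hypoxia 0 h, the real count by limma was 0 and the highest other 0, so 10 of 10 splits gave as many.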
